A study of Mus musculus with 15 samples.

How the data were processed

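Total RNA was extracted from 20 mg of mouse skeletal muscle, and poly(A) libraries were made with a strand-specific kit and sequenced as single reads of 75 bases, per the labels' protocols. The labels assign 5 libraries to each of wild type, heterozygote and homozygote, 15 in all. They do not say which muscle was taken, nor whether each library came from a separate animal. The p-values therefore measure the spread between these samples. The submitters' processing notes name bcl2fastq, cutadapt, STAR and DESeq2 and the build GRCm39, without versions or settings. How reads were counted, and whether strand was used, is not given in the sources used here.

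The data analysed are 1 table of comparisons made by the authors. Its mean normalized count per gene, a signal averaged over all libraries after the authors' scaling, is given per the file headers as the base mean. The log2 fold changes and their standard errors were deposited by the authors for 3 pairs of genotypes. Each fold change equals its statistic times its error, which does not tell whether shrinkage was used. A value as large as 21.6, for Ighv3-1 in homozygotes against wild type in the authors' deposited table, speaks against strong shrinkage. The deposited Wald statistic is a score, the log2 fold change divided by its standard error. The deposited p-values are those of the normal distribution for that score, and the deposited adjusted p-values were recomputed here as Benjamini-Hochberg values over the genes that have one. No p-value is given for 39 genes; in DESeq2, the tool named in the submitters' processing notes, this is the default where a library lies far from its group. The authors' table also has no adjusted p for 658 genes in homozygote against wild type, all with a mean count of 4.32 or less, and for 329 genes in homozygote against heterozygote, all with a mean count of 3.78 or less. The lowest mean count listed is 3.24. The 3 fold changes of a gene add up within 0.001 except for 2 genes.

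The table has 0 columns of per-library values. The tests, gene lists and naming rule were chosen before the data were examined, but the tests needed counts per library and were not run as chosen: fits of each comparison with edgeR were not made, and neither were a block by replicate number, the omission of each library in turn, surrogate variables, principal components, a check for duplicate libraries or an inter-gene correlation estimated from the data. The authors' own Wald tests took the place of the planned fits, with the same threshold of 0.05 on the adjusted p. The depth per library is unknown, and the precision of each value is the deposited standard error. Intervals of 95% are the log2 fold change plus or minus the normal quantile times that error.

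From the 3 standard errors of a gene the variance of each genotype's level was solved. A linear trend over 0, 1 and 2 mutant alleles, weighted by these variances, and the distance of the heterozygote from the midpoint of the other genotypes were tested with Wald tests and Benjamini-Hochberg adjustment over 16995 genes. The same variances were used to simulate unchanged genotypes in 100 draws. These variances assume that the errors of the 3 comparisons come from a single fit with separate libraries per genotype, and all came out above 0.

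Gene lists numbered 40. A list was tested where at least 3 members had a p-value, which left 38, with the competitive set test cameraPR of limma 3.58.1 in R 4.3.3 on the Wald statistics, an assumed inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. The highest assumed correlation at which a call held is given in the paragraph of the call for the lists fixed in advance, since statistics alone do not allow an estimate. A list's median is that of the deposited log2 fold changes of its measured members. A further 7 lists of immune and lymphatic cell types were written after the called genes had been seen and are used only in the closing section. Symbols were taken from the table; 16696 of its gene IDs were also in a reference list of symbols, 16249 of them with the same symbol. Where 2 gene IDs share a symbol, the more abundant was used.

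Genes named in the text follow a rule. It takes Chchd10 and the measured creatine genes, up to 8 called genes with the largest change in each direction, up to 4 members with the lowest p of each list described, and the 5 genes with the lowest p of the trend outside the second group. The second group was limited to genes with a log2 CPM of at least 1, for which the mean count as a share of the summed mean counts stood in, and excluded predicted-gene and clone names. Where fewer than 5 genes were called, the 5 genes with the lowest p that met the same limits are given. Reads of immunoglobulin segments and of the haemoglobin genes can be shared between near-identical copies, so their single values are uncertain. The reference annotation in hand is of another build, so coordinates are those of the table.

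Alternatives were the adjustment over all genes with a p-value, p-values from a t distribution with 12 degrees of freedom, statistics divided by their robust spread, protein-coding genes only, a test against a fold change of 1.2, thresholds of 0.1 and 0.01, the omission of lymphoid genes, a mean count of at least 10 or 100, and other settings of the set test. The steps were tested on simulated estimates with known changes on the real genes' errors. In heterozygote against wild type, with 200 of 16995 genes changed, 43.6% of changes of 0.5 on the log2 scale, 70.6% of changes of 1 and 91.5% of changes of 2 were recovered, and 4.81% of calls were false. In homozygote against wild type the shares were 44.5%, 69.0% and 92.5%, with 4.95% false. The noise was drawn from the same errors that the test used, so a false share near the threshold follows from the construction. Recovery would differ with another number of changed genes or another spread of the statistics. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.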

Results

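Poly(A) RNA was sequenced from mouse skeletal muscle of 3 genotypes at the Chchd10 locus, with 5 libraries each from wild-type, heterozygous and homozygous muscle. The mutation, called G66V in the series' design text, lies in CHCHD10, a small protein of the mitochondrial intermembrane space. The question named by the series is whether the number of mutant alleles sets the size of the response and whether creatine metabolism is involved. The authors' deposited table lists 17034 genes with a mean normalized count over the 15 libraries and, for each pair of genotypes, a log2 fold change, its standard error, a Wald statistic and p-values. It holds no value for a single library. The depth per library is not in the table, nor is the spread between replicates, and the errors below are the authors' standard errors. The mean normalized counts of the listed genes sum to 2.25e+07, and 12.6% of this sum comes from mitochondrial genes. Errors were smaller for abundant genes: the median standard error of the log2 fold change was 0.10 for genes with a mean count of at least 100 and 0.16 over all genes in homozygote against wild type.

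The transcript of the mutated gene itself did not differ between genotypes by more than its error. Chchd10 (ENSMUSG00000049422.8, GRCm39 chromosome 10, 75768964 to 75773581, plus strand) had a mean normalized count of 5500.2 in the authors' deposited table. There its log2 fold change was 0.01 with a standard error of 0.07 in heterozygotes and -0.03 with a standard error of 0.07 in homozygotes against wild type. The 95% intervals ran from -0.13 to 0.15 and from -0.17 to 0.11. Because the mutant allele carries a substitution, these values describe total transcript and do not separate the alleles.

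Of the 7 genes listed for creatine synthesis, uptake and use, 6 were measured, and none passed the threshold in any comparison, over all genes or adjusted over the list alone. The member with the lowest p was Gatm, which encodes the enzyme of the initial step of creatine synthesis. In the authors' deposited table Gatm had a log2 fold change of 0.53 (standard error 0.22, unadjusted p = 0.0138, adjusted p = 0.453) in homozygotes against heterozygotes. The authors' deposited table has 0.35 (standard error 0.21) for Gatm in homozygotes and -0.18 (standard error 0.22) in heterozygotes against wild type. Gamt, which completes the synthesis, stood at 0.20 (standard error 0.31) and the creatine transporter Slc6a8 at -0.01 (standard error 0.11) in homozygotes against wild type in the authors' deposited table. Muscle creatine kinase Ckm, at a mean normalized count of 224683, had a log2 fold change of -0.08 (standard error 0.13) in that comparison of the authors' deposited table. Mitochondrial Ckmt2 was at -0.02 (standard error 0.27) and brain-type Ckb at 0.30 (standard error 0.21) there, again from the authors' deposited table. The set test gave an adjusted p of 0.802, 0.591 and 0.455 for this list in heterozygote against wild type, homozygote against wild type and homozygote against heterozygote. In homozygotes against wild type the 95% interval ran from -0.07 to 0.78 for Gatm and from -0.24 to 0.21 for Slc6a8.

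**Figure D1:**
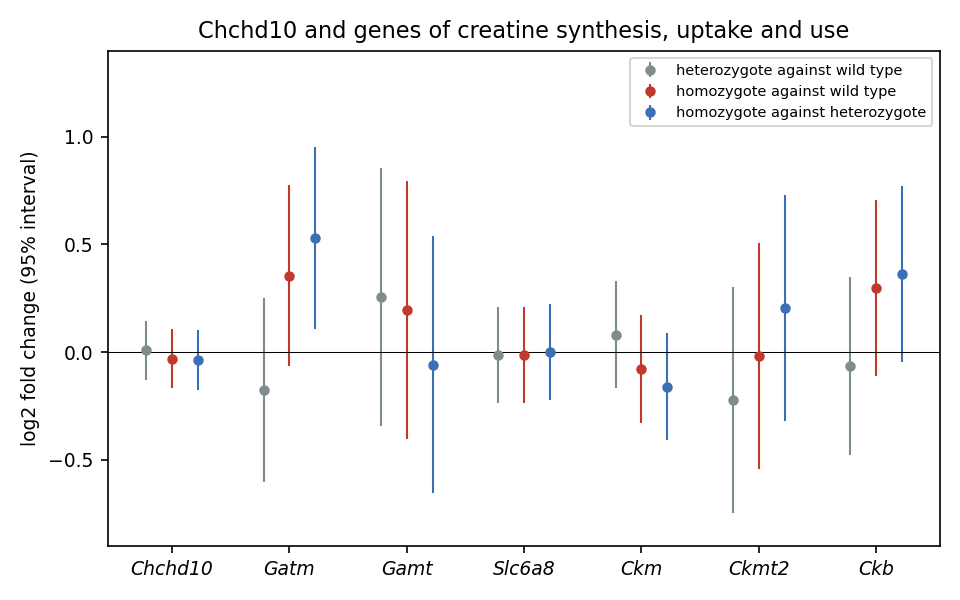
Log2 fold changes of Chchd10 and the 6 measured creatine genes (x axis) in the 3 comparisons of the authors' deposited table, with bars for 95% intervals from its standard errors. The interval excludes 0 only for Gatm in homozygotes against heterozygotes, where the log2 fold change was 0.53.

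The comparison of heterozygous with wild-type muscle asks what 1 mutant allele does. Genes of tendon were lower as a group: 1 of the 8 measured members had a positive log2 fold change, and the median was -1.39. In the authors' deposited table Kera, a proteoglycan of tendon and cornea, stood at -1.48 (standard error 0.57), Mkx, a tendon transcription factor, at -1.40 (standard error 0.65), Tnmd, a tendon membrane glycoprotein, at -1.16 (standard error 0.54) and Thbs4 at -0.69 (standard error 0.39). Interferon-induced genes also fell as a group, with a median of -0.67 over 19 measured members, 1 of them positive. The authors' deposited table gives -0.47 (standard error 0.16) for Rigi, a cytosolic sensor of RNA, -1.09 (standard error 0.47) for Ifit1, -0.67 (standard error 0.30) for Ifit2 and -0.86 (standard error 0.43) for Oasl2. Genes of fatty acid uptake and oxidation fell as a group by a smaller amount, with a median of -0.20 over 29 members. Among them were the medium-chain dehydrogenase Acadm at -0.22 (standard error 0.25) and Echs1 at -0.15 (standard error 0.17) in the authors' deposited table. Slow fibre genes had a lower median, -0.40 with none of 15 positive, and fast fibre genes had 15 of 17 positive (median 0.10), but neither list passed the set test on the statistics (adjusted p = 0.0854 and 0.154). The slow fibre list passed with ranks (adjusted p = 0.0209) and with log2 fold changes (1.77e-05) in place of the statistics. Targets of the endoplasmic reticulum unfolded protein response rose as a group (median 0.07, 15 of 17 positive), among them Sdf2l1 at 0.44 (standard error 0.19) in the authors' deposited table. Cytosolic heat shock genes also rose as a group (median 0.09, 11 of 16 positive), with Dnaja1 at 0.19 (standard error 0.11) in the authors' deposited table. Markers of other cell types leaned lower without passing: endothelium (median -0.14, 0 of 9 positive, adjusted p = 0.0586), smooth muscle and pericyte (-0.22, 1 of 8, 0.0676) and fibroblast and matrix (-0.07, 2 of 12, 0.0839).

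No single gene passed an adjusted p of 0.05 in that comparison, in the authors' Wald test (DESeq2) with Benjamini-Hochberg adjustment, and no member of the 5 lists called passed when adjusted over the list alone. At an unadjusted p below 0.05 the authors' deposited table has 292 genes, 114 higher and 178 lower, where 849.8 would be expected by chance if the statistics had unit spread. The lowest p among genes of sufficient abundance, none past the threshold, belonged to Fgf6, a growth factor of muscle (log2 fold change -0.36, p = 0.000117), Fat4 (-0.43), the leptin receptor Lepr (-0.96), the matrix protein Tnc (-1.16) and Fam3c (-0.29), with an adjusted p of 1.000 for each in the authors' deposited table. The set test called 5 of 38 lists: tendon (adjusted p = 4e-09), interferon response (5.88e-13), fatty acid uptake and oxidation (0.00219), the unfolded protein response (0.00219) and heat shock (0.0184). An inter-gene correlation could not be estimated from this table, and the calls held up to an assumed correlation of 0.45, 0.39, 0.04, 0.05 and 0.02 in that order. With log2 fold changes in place of statistics the unfolded protein response and heat shock calls were lost; endothelium passed with ranks (adjusted p = 0.0209) and at a mean count of at least 10 (0.0471), and smooth muscle and pericyte with ranks (0.0227).

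Homozygous against wild-type muscle asks what 2 mutant alleles do, and the lymphocyte list had the largest median among the lists that passed the set test. Of the 26 genes called, 9 belong to a set of lymphoid genes that was drawn up after the calls had been seen. Of the genes named by rule, the authors' deposited table has log2 fold changes of 2.05 (standard error 0.47, adjusted p = 0.0169) for Cd52, a surface glycoprotein of lymphocytes, 1.55 (standard error 0.36, adjusted p = 0.0188) for Ikzf1, a transcription factor of lymphoid development, and 1.46 (standard error 0.32, adjusted p = 0.0110) for the leukocyte tetraspanin Cd37. Coro1a, an actin regulator of leukocytes, was at 1.27 (standard error 0.30, adjusted p = 0.0208) and the kinase Syk, which signals from the B cell receptor, at 1.08 (standard error 0.27, adjusted p = 0.0428) in the authors' deposited table. All 9 measured members of the lymphocyte list were positive, with a median of 2.15, and 2 passed over all genes while 8 passed adjusted over the list alone. These were led in the authors' deposited table by the B cell surface protein Ms4a1 at 2.63 (standard error 0.52, adjusted p = 0.00341), followed by Cd79a at 2.33 (adjusted p = 0.0685) and the T cell coreceptor Cd4 at 1.53 (adjusted p = 0.0685). These genes were of low abundance, Ms4a1 having a mean normalized count of 32.1 in the authors' deposited table.

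Macrophage genes rose as a group in homozygotes, with a median of 0.59 and all 10 members positive. Among them the authors' deposited table gives 0.73 (standard error 0.24) for lysozyme Lyz2, 0.65 (standard error 0.23) for the complement gene C1qc, 0.72 (standard error 0.31) for C1qb and 0.69 (standard error 0.30) for Cd68, and 2 members passed adjusted over the list alone. Genes of Schwann cells and nerve were all positive too, 7 of 7 with a median of 0.35. White adipocyte genes fell as a group (median -0.35, none of 10 positive), as did slow fibre genes (median -0.41, 3 of 15 positive) and circadian clock genes (median -0.08, 4 of 18 positive). For these the authors' deposited table lists -0.67 (standard error 0.46) for Pck1, -1.46 (standard error 1.35) for the slow myosin heavy chain Myh7 and -0.61 (standard error 0.28) for Per1. Slow fibre genes had a similarly low median in heterozygotes, set against the same wild-type libraries. Uneven shares of fat, nerve or slow fibres between pieces of muscle were not separated from an effect of genotype.

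The 4 genes that fell in homozygotes past the threshold were abundant and changed little. The authors' deposited table has log2 fold changes of -0.36 (standard error 0.07, adjusted p = 0.00374) for the transcription factor Zfhx3, -0.21 (standard error 0.05, adjusted p = 0.0428) for the nuclear protein Nucks1, -0.21 (standard error 0.05, adjusted p = 0.0430) for the forkhead factor Foxn3 and -0.19 (standard error 0.04, adjusted p = 0.00341) for the kinesin Kif13a. Their mean normalized counts in the authors' deposited table lay between 817.7 and 3757.

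In all, 26 genes passed in homozygote against wild type, 22 higher and 4 lower. At an unadjusted p below 0.05 the authors' deposited table has 855 genes, 634 higher and 221 lower, against 849.8 by chance at unit spread. The robust spread of these statistics was 0.87, so that chance number is too high. The set test called 6 of 38 lists: lymphocyte (adjusted p = 9.91e-18), macrophage (3.78e-07), Schwann cell and nerve, white adipocyte, slow fibre and circadian clock (0.0238 each). The first 2 calls held up to an assumed correlation of 0.93 and 0.31, and the other 4 only up to 0.02 or 0.03. The circadian call was lost with ranks (adjusted p = 0.0521), and it and the Schwann cell and nerve call were lost with log2 fold changes in place of statistics. The count of 26 genes became 0 with p-values from a t distribution with 12 degrees of freedom, 194 with statistics divided by their robust spread, and 12 without lymphoid genes. The lymphoid set holds receptor segments and members of marker lists only, so other leukocyte genes can remain among the 12. A further 39 genes have no p-value in the authors' deposited table, 36 of them highest in homozygotes, and these include all 6 measured genes of the blood list (median 1.51) and 16 immunoglobulin segments.

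**Figure D2:**
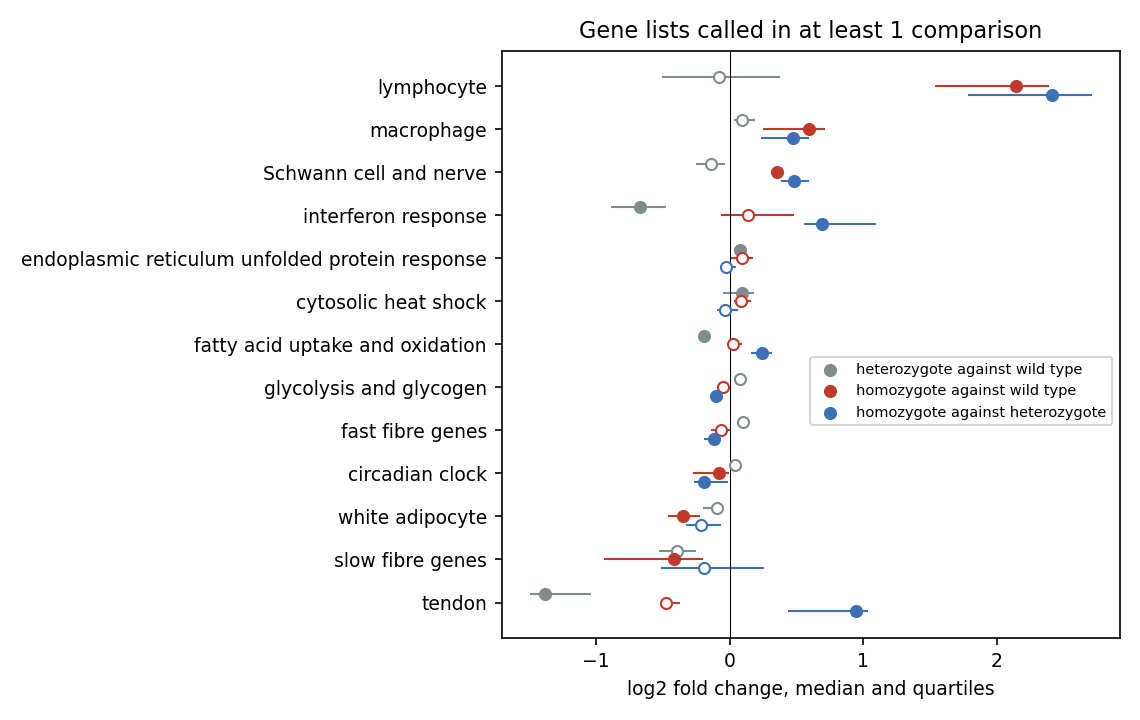
Median (point) and quartiles (line) of the members' log2 fold changes (x axis) for each gene list called in at least 1 of the 3 comparisons, computed from the authors' deposited table. Filled points passed the set test at an adjusted p below 0.05; the lymphocyte list lies at 2.15 and 2.41 in the 2 homozygote comparisons and at -0.08 in heterozygotes.

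The homozygote and heterozygote effects were set against each other directly in homozygote against heterozygote. Here 85 genes passed, 79 higher and 6 lower in homozygotes. At an unadjusted p below 0.05 the authors' deposited table has 1094 genes, 756 higher and 338 lower, against the same 849.8 by chance at unit spread. The robust spread of these statistics was 0.95. The genes with the largest rise among those named by rule were again leukocyte genes. The authors' deposited table has 2.27 (standard error 0.46, adjusted p = 0.00144) for the lymphocyte GTPase Gimap3, 1.81 (adjusted p = 0.0289) for Cd52, 1.61 (adjusted p = 0.0155) for the integrin Itgal, 1.52 (adjusted p = 0.0155) for Rac2 and 1.50 (adjusted p = 0.00301) for Cd37. The authors' deposited table also has Ikzf1 at 1.49 (adjusted p = 0.0147), the pan-leukocyte phosphatase Ptprc at 1.46 (adjusted p = 0.0106) and Wdfy4, needed for cross-presentation by dendritic cells, at 1.32 (adjusted p = 0.00618). The 6 lower genes of the authors' deposited table were Tln2 (-0.30), which links integrins to actin, Zfhx3 (-0.28), Speg (-0.21), a kinase of the muscle triad, Kif13a (-0.19), Myom1 (-0.19), which crosslinks myosin at the M band, and Dennd4b (-0.14). Lymphocyte genes had a median of 2.41, with 5 of 9 members past the threshold over all genes and 6 adjusted over the list alone.

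Interferon-induced genes were higher as a group in homozygotes than in heterozygotes, with a median of 0.69 and all 19 members positive. Against wild type this list was not called in homozygotes, while it was lower in heterozygotes. The authors' deposited table has 0.53 (standard error 0.16) for Rigi, 1.97 (standard error 0.66) for Mx1 and 2.17 (standard error 0.80) for Zbp1, and 3 members passed adjusted over the list alone. Tendon genes (median 0.95, 8 of 8 positive), fatty acid genes (0.24, 27 of 29), macrophage genes (0.48, 9 of 10) and genes of Schwann cells and nerve (0.48, 7 of 7) were likewise higher as groups. Against wild type the fatty acid genes had a median of 0.03 in homozygotes (set test adjusted p = 0.978) and -0.20 in heterozygotes. Genes of glycolysis and glycogen fell as a group (median -0.10, 1 of 20 positive), with the muscle glycogen phosphorylase Pygm at -0.28 (standard error 0.13) and Pfkm at -0.16 (standard error 0.08) in the authors' deposited table. Fast fibre genes (median -0.12, 3 of 17 positive) and circadian clock genes (-0.19, 5 of 18) fell as groups too, with the fast myosin heavy chain Myh4 at -0.42 (standard error 0.24) and Nr1d2 at -0.18 (standard error 0.08) in the authors' deposited table. The set test called these 9 lists, with an adjusted p of 2.75e-16 for lymphocyte, 2.3e-10 for interferon response and between 0.00148 and 0.0192 for the other 7. Only the lymphocyte and interferon calls held at an assumed correlation of 0.1, up to 0.84 and 0.29. The others held up to 0.09 for macrophage and for Schwann cell and nerve, 0.07 for glycolysis, 0.05 for circadian clock, 0.04 for tendon and for fast fibre and 0.02 for fatty acid genes. With log2 fold changes in place of statistics the lymphocyte, interferon and tendon calls alone remained. The count of 85 genes became 0 with the t distribution, 48 without lymphoid genes and 156 with statistics divided by their robust spread.

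Whether the response followed the number of mutant alleles was tested from the deposited fold changes and errors, with alleles scored 0, 1 and 2. A linear trend passed for 54 genes, 49 rising and 5 falling with allele number. All 26 genes called in homozygote against wild type were among them, which follows largely from how the slope is built. With scores of 0, 1 and 2 and similar errors, the slope rests almost wholly on the difference between homozygote and wild type. At an unadjusted p below 0.05 the trend had 870 genes, against 849.8 by chance at unit spread, a number too high where the spread is below 1. The 5 genes named for the trend were genes of B cells and antigen presentation: H2-Ob and H2-DMb2, which encode parts of the antigen-loading machinery, Ms4a1, the chemokine receptor Cxcr5 and the transcription factor Pax5. Their slopes per allele were 1.16 for H2-Ob, 1.12 for H2-DMb2, 1.36 for Ms4a1, 1.26 for Cxcr5 and 1.11 for Pax5, with adjusted p between 0.00142 and 0.00621. For the creatine and complex I lists the set test gave an unadjusted p of 0.329 and 0.321 for the trend. It gave 0.327 and 0.308 in homozygote against wild type. The trend is therefore not a separate test of dose, and it passes also where only homozygotes differ. The higher trend genes had a median log2 fold change of -0.01 in heterozygotes and 1.68 in homozygotes. The heterozygote level was below the midpoint of the other genotypes for the lymphocyte list (median distance -1.27, set test adjusted p = 1.27e-07), a call that held up to an assumed correlation of 0.37. The set test called 10 of 38 lists off the midpoint in all, among them interferon response (median -0.76, adjusted p = 2.5e-15), tendon (-1.17, 3.35e-06), fatty acid uptake and oxidation (-0.22, 0.00123), glycolysis and glycogen (0.09, 0.00123) and complex IV (-0.08, 0.0482). These 5 calls held up to an assumed correlation of 0.40, 0.34, 0.05, 0.06 and 0.01 in that order. No single gene departed from the midpoint at an adjusted p below 0.05 (Wald test from the deposited errors), and 599 did at an unadjusted p below 0.05, fewer than the 849.8 expected by chance at unit spread. The number of trend genes was 0 with the t distribution, 226 with statistics divided by their robust spread and 22 without lymphoid genes.

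Across 16995 genes, which are not independent replicates, the 2 sets of log2 fold changes against the same wild-type libraries had a Pearson correlation of 0.30 and a Spearman correlation of 0.31. Unchanged groups simulated against shared controls, from the genotype variances that the deposited errors imply, gave a mean correlation of 0.51 with a range of 0.46 to 0.55 in 100 draws. The covariance was 0.0327 against a simulated 0.0517, a difference of -0.0190, and the signs were the same for 60.8% of genes against 66.8% simulated. The observed values lay below the simulated range, and the Wald statistics of heterozygote against wild type had a standard deviation of 0.80 where 1 would be expected, so the deposited errors were larger than the scatter of that comparison. No overlap of calls could be counted between these comparisons, because heterozygote against wild type had none. The homozygote comparisons, which share their homozygous libraries, had 16 higher and 2 lower genes in common. In 100 simulated draws of unchanged genotypes with the same shared libraries at most 2 and 1 genes were called and 0 were shared, so few calls that the draws set no scale for an overlap of longer lists.

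**Figure D3:**
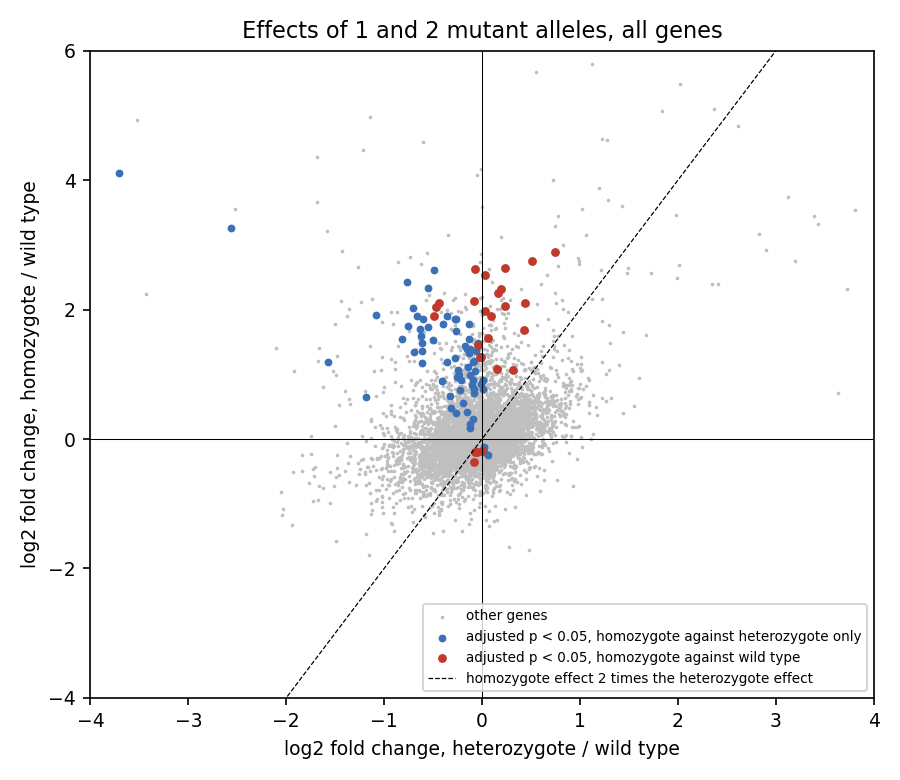
Log2 fold change of each gene against wild type in heterozygotes (x axis) and homozygotes (y axis), from the authors' deposited table, with 10 genes outside the axes. Genes called in homozygotes against wild type (red) had a median of 0.03 in heterozygotes, and those called only against heterozygotes (blue) lie to the left because that comparison selects for low heterozygote values. The dashed line marks a homozygote effect 2 times the heterozygote effect.

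Lists for the mitochondrial functions tied to CHCHD10 did not pass the set test on the statistics in any of the 3 comparisons, but respiratory chain genes leaned lower in heterozygotes. There 6 of 36 complex I genes, 0 of 13 of complexes II and III and 2 of 15 of complex IV had a positive log2 fold change, with medians of -0.04, -0.06 and -0.06. With ranks in place of statistics these lists passed in heterozygotes (adjusted p = 0.0421, 0.0223 and 0.0212), as did ATP synthase (0.0388) and the tricarboxylic acid cycle (0.0126). In homozygotes against heterozygotes 34 of 36, 13 of 13 and 15 of 15 were positive, with medians of 0.05, 0.06 and 0.07, and these lists passed upward with ranks (adjusted p = 0.00344, 0.0438 and 0.0109). Slow fibre and fatty acid genes also had lower medians in heterozygotes than in wild type, and the labels do not name the muscle. A difference in fibre type between pieces of muscle was not separated from these leans. In homozygotes against wild type the median log2 fold change was 0.02 for 36 nuclear subunits of complex I, 0.01 for 13 of complexes II and III, 0.02 for 15 of complex IV and -0.0003 for 16 of ATP synthase. It was -0.05 for 8 mitochondrially encoded subunits, -0.0001 for 20 CHCHD10 partners and cristae proteins and -0.03 for 18 mitochondrial chaperones and proteases. Among the partners the authors' deposited table gives 0.09 (standard error 0.07) for Micos10 and -0.06 (standard error 0.06) for Chchd3, both parts of the complex that shapes cristae. Targets of the integrated stress response had a median of -0.01 over 30 measured members, none of which passed over all genes or adjusted over the list alone. Slc7a5, an amino acid transporter among them, stood at 0.61 (standard error 0.31) and Sesn2 at 0.27 (standard error 0.16) in homozygotes against wild type in the authors' deposited table. Medians for the denervation response (23 members, -0.05), the neuromuscular junction (19, 0.03), muscle atrophy (24, 0.03), muscle stem cells and regeneration (14, -0.07) and the tricarboxylic acid cycle (21, -0.02) were also near 0 in that comparison, with no call. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y lay between -0.05 and 0.05 in homozygotes against wild type in the authors' deposited table.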

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

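The lists of immune cells and the tests below were chosen after the called genes had been seen; the tests of the lymphocyte and of the abundant, falling genes were written down before the values that decide them were seen, and the tendon test after standard errors of its members had been seen.

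The homozygote and heterozygote effects against the same wild type differed for 85 genes, by the deposited test of homozygote against heterozygote. By the same test, the authors' deposited table has log2 differences of 2.27 for Gimap3, 1.81 for Cd52, 1.61 for Itgal, 1.52 for Rac2, 1.50 for Cd37, 1.49 for Ikzf1, 1.46 for Ptprc and 1.32 for Wdfy4. Lower in homozygotes than in heterozygotes in the authors' deposited table were Tln2 (-0.30), Zfhx3 (-0.28), Speg (-0.21), Kif13a (-0.19), Myom1 (-0.19) and Dennd4b (-0.14). Among lists, the set test of that difference gave medians of 2.41 for lymphocyte, 0.95 for tendon, 0.69 for interferon response, 0.48 for macrophage, 0.48 for Schwann cell and nerve, 0.24 for fatty acid uptake and oxidation, -0.10 for glycolysis and glycogen, -0.12 for fast fibre and -0.19 for circadian clock genes.

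Lymphocyte genes rose in homozygotes with added lists of B cell (median 2.10, 21 genes, 5 of them in the lymphocyte list) and T cell genes (1.52, 21 genes, 4 in that list). A lymph node carried along stays open, though the 8 measured of 16 lymph node stroma genes did not rise as a group. Their median of -0.0641 lay below the bound of 0.2 set beforehand, and their upper quartile was 0.0912. That bound was wrong for Clu, Enpp2 and Ltbr, whose mean counts of 1293.6, 433.6 and 389.7 in the authors' deposited table would hide a small share of node. Abundance was put forward for these genes only, and does not account for the low upper quartile of the list. Among added lists, dendritic cell (median 0.93), plasma cell (0.82) and germinal centre genes (0.67) were higher and lymphatic endothelium (-0.31) was lower, which go both ways. Blood left in the tissue may account for part of it: the median of the blood list was 1.51, on 6 genes without a p-value, while the neutrophil genes S100a8 and S100a9 (mean counts 6.88 and 8.14) stood at 0.27 and 0.49 in the authors' deposited table. Lymphocyte RNA in some libraries and not in others stays open too: the median estimated dispersion of the B cell list, 0.310 against 0.0586 for matched lists, lay at percentile 100 of 10000 such lists, but 25 of the 38 lists tested lay above percentile 95, among them 13 of 25 that were not called. Of the 84 listed immunoglobulin segments 16 have no p-value, against 39 of all 17034 listed genes. By default in DESeq2 this marks an extreme count in at least 1 library, which goes with such an uneven share. Inflammation with fibre damage stays open, with 1 of 4 lists (macrophage) risen, and so does an effect of the homozygous genotype, which a table without single libraries cannot tell apart from a few libraries rich in lymphocytes.

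The 4 genes lower in homozygotes were abundant, with lengths from 25788 bases for Nucks1, near the median of 19091.5 over all listed genes, to 1018987 for Zfhx3. Dilution of muscle RNA by lymphocyte RNA, which would lower abundant genes together, is argued against as the sole cause: 2808 genes with a mean count of at least 1000 had a median log2 fold change of -0.0209 (quartiles -0.07 and 0.02) against -0.21 for the 4 genes, a gap that scaling, being the same for all genes of a library, does not make. The median near 0 alone says nothing, since the authors' scaling can hold it there with or without dilution. The 4 genes were picked for passing downward, which widens the gap, so a small part from dilution is not excluded. Gene length is a candidate explanation for the direction, since the statistics of homozygote against wild type fell with genomic length (Spearman correlation -0.19 across genes) and the median length of the 4 genes, 277143 bases, lay above that of 99.98% of matched lists. The same correlation was -0.06 in heterozygote against wild type and -0.12 in homozygote against heterozygote. With exonic length the correlation in homozygote against wild type was -0.22. How much of the size length explains was not settled. The 1822 genes at least as long as the shortest and as abundant as the least abundant of the 4 had a median of -0.05, with 74.3% negative. That set reaches down to 25788 bases, far below the median length of the 4 genes, which were also picked for passing downward. An effect of genotype was not separated from length.

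Tendon genes were lower in heterozygotes (median -1.39), and in homozygotes they had a median of -0.48 with 1 of 8 positive (unadjusted p = 0.0419 and adjusted p = 0.177, or 0.00951 with log2 fold changes). Their median estimated dispersion was 0.408 against 0.0146 for matched lists, at percentile 100 of 10000 lists, but this value follows from errors already seen and is not particular to tendon. The interferon list, also lower in heterozygotes, lay at percentile 100, and the creatine list, which was not called, at 98.93. The slow fibre and white adipocyte lists, called in homozygotes, also lay at percentile 100, and Schwann cell and nerve at 99.97. Both mutant genotypes were set against the same wild-type libraries. Uneven amounts of tendon between pieces of muscle, wild-type ones included, and an effect of genotype both stay open.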

How the results depend on the processing

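No paired analysis was possible because the table holds no column for a single library, so replicate numbers cannot enter a fit. For the same reason the planned scalings, filters on counts, fits on 2 genotypes, left-out libraries, surrogate variable, sex covariate, estimated correlation, split controls and other splits of the libraries were not run, and how many genes other splits of the libraries give is unknown. Of the planned settings, a mean count of at least 10 was run; the others were chosen after seeing the table.

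The number of genes in homozygote against wild type (26), homozygote against heterozygote (85) and the trend (54) became 0, 0 and 0 with a t distribution, 194, 156 and 226 with statistics divided by their robust spread, 2, 21 and 5 against a fold of 1.2, 12, 48 and 22 without lymphoid genes, 84, 166 and 112 at an adjusted p below 0.1, and 4, 29 and 13 below 0.01. The fewer genes under the t distribution, the stricter thresholds and the minimum fold follow from their construction, as do the more genes at 0.1. The robust spreads in homozygote against wild type and against heterozygote were 0.87 and 0.95, so dividing by them raises the statistics and the counts. Omitting lymphoid genes takes out 9, 19 and 14 of the called genes and can leave leukocyte genes outside the marker lists. The cause of the other shifts was not tested. With the robust spread, heterozygote against wild type had 1 gene and the midpoint test 2, in place of 0. With protein-coding genes alone they were 28, 88 and 74 (25, 79 and 51 of them shared with the counts above), and with a mean count of at least 10 they were 24, 73 and 57 (24, 73 and 48 shared).

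Lists called in heterozygote against wild type went from 5 to 3 and 2 at assumed correlations of 0.05 and 0.1 and to 14 with ranks. In homozygote against wild type they went from 6 to 2 and 2, and in homozygote against heterozygote from 9 to 2 at 0.1 and to 3 with log2 fold changes; the cause was not tested. The correlation of the heterozygote and homozygote effects was 0.33 without lymphocyte genes and 0.22 at a mean count of at least 10, against 0.30. Chchd10 stayed far from the threshold in each setting, and all 23 called values of genes named by rule missed it with the t distribution.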

Other observations

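Among the genes without a p-value are genes induced by interferon gamma. In the authors' deposited table the interferon-gamma-induced GTPases Irgm1 (1.29), Irgm2 (1.75), Igtp (1.96), Iigp1 (2.82), Gbp6 (1.45) and Gbp7 (0.78) were higher in homozygotes than in wild type on the log2 scale, with the checkpoint ligand Cd274 (0.88). They were named after their values had been seen, and no list or test was fixed for them. The interferon response list fixed in advance was not called in homozygotes against wild type. Of the 39 such genes 36 were highest in homozygotes, against 37.0% of all other genes. In DESeq2, which the submitters' processing notes name, a missing p-value by default marks a gene with an extreme count in at least 1 library, so these 39 genes are picked for such libraries and their high values need not hold for the group. The haemoglobin genes Hba-a1 (1.53), Hbb-bs (1.38) and Hbb-bt (1.79) and the erythroid gene Alas2 (1.50) of the authors' deposited table belong to the same 39.

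Immunoglobulin segments were higher in homozygotes than in wild type for 77 of 84 listed segments, with a median log2 fold change of 2.68, and in heterozygotes for 43, with a median of 0.05. No gene with a mean count below 3.24 over all libraries is listed, so a rare segment is listed more easily if homozygotes raise its mean. The count and median therefore lean toward homozygotes, and 16 of the 84 segments have no p-value. In homozygotes 1 segment passed against wild type and 4 against heterozygotes. The added list of germinal centre and proliferation genes had a median of 0.67, with 13 of 13 positive, 1 past the threshold over all genes and a set test adjusted p of 9.69e-09 over the 7 added lists, a call that held up to an assumed correlation of 0.61. The list mixes genes of B cells with genes of dividing cells, and no test separated these. In the authors' deposited table Mki67 stood at 1.54 (standard error 0.40, adjusted p = 0.0629) and Pclaf at 2.10 (standard error 0.53, adjusted p = 0.0459). The added list of lymphatic endothelium fell in both mutant genotypes, with medians of -0.39 in heterozygotes and -0.31 in homozygotes and adjusted p of 0.000367 and 0.0198, calls that held up to an assumed correlation of 0.27 and 0.09. These lists were written after the called genes had been seen.

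Genes near the mutated locus did not stand out. Within 10 Mb on each side of Chchd10 the table lists 245 genes, of which 0 passed in homozygote against wild type and 3.27% had an unadjusted p below 0.05, against 5.06% elsewhere. In homozygote against heterozygote 1 of them passed, Arhgap45, a leukocyte GTPase activator, at 1.00 (standard error 0.27, adjusted p = 0.0440) in the authors' deposited table.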
